A study of Serratia marcescens with 2 samples.

How the data were processed

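Gene expression was measured by RNA sequencing in 2 strains of *Serratia marcescens*, the wild type JNB5-1 and the mutant SK68, each grown for 4 h at 30 °C. Per the labels' protocols, total RNA was extracted with a column kit, rRNA was removed and cDNA libraries were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name FastQC 0.10.1, cutadapt 1.9.1, Bowtie2 2.1.9 and HTSeq, with no role, order or further setting; the genome build and annotation are not given in the sources used here. The strandedness of the counting is likewise not given, so reads of overlapping or antisense genes could not be told apart.

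The deposited table holds 4907 genes with locus tag, symbol or tag as name, start, end, length and product. Per the file headers, the authors gave 1 count column for each strain, whole numbers of reads per gene that were not normalized. The series description speaks of triplicate sequencing, and whether each column pools 3 libraries or shows 1 is not stated. The authors' FPKM values equal the count divided by gene length and by the total of the same column, on the usual FPKM scale, within 0.005. The authors' log2 fold changes, SK68 over JNB5-1, equal those of edgeR's exact test on the deposited counts with TMM scaling to within 5e-10. The authors' p-values are unadjusted and equal those of the same test with a preset dispersion of 0.1 to within 4.9e-08, so they rest on an assumed and not on a measured spread, and compare these libraries and not the conditions. The design fixed beforehand called for adjusted p-values; the table has unadjusted ones, so the Benjamini-Hochberg adjustment was computed over all its genes, and a gene counts as called at an adjusted p of 0.05 and 2-fold.

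The log2 ratio of SK68 over JNB5-1 was computed from the deposited counts after TMM scaling (edgeR 4.0.16, R 4.3.3), with a pseudocount of 1, for genes with at least 10 counts over both strains. Of the 4907 genes, 637 had 0 counts in both strains and 126 more were below this minimum, which left 4144. With 1 column per strain no test across genes was made here. The 95% intervals of ratios are exact (Clopper-Pearson) binomial intervals of the share of a gene's reads in SK68; those of list medians are binomial intervals from ranked members. Sequenced reads are not independent molecules, so the intervals and the floor cover counting error only. For a gene at 0 counts in one strain the ratio depends on the pseudocount; such ratios enter list medians and plots and are not given in the text. A count of 0 allows up to 3 counts, which is 0.326 CPM in JNB5-1 and 0.302 CPM in SK68. Total depth was 9214184 and 9946151 counts, the 20 most counted genes took 23.7% and 25.1%, and rRNA and tRNA genes 0.0350% and 0.0328%.

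Before the data were examined, 26 gene lists were fixed, matched by symbol. For each with at least 3 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries only. The random genes were drawn from all compared genes in these bins. The percentile and the interval of a median thus treat members as separate draws, and neither allows for adjacent genes that vary together. Of the lists, 22 were described in this way. The other 4, fimbriae and surfactant and acetoin with 0 measured members, type VI secretion with 1 and secreted enzymes with 2, had too few by symbol. The rule for named genes, fixed at the same time, takes the 12 genes with the highest and the 12 with the lowest ratio among the calls whose larger count reaches the median of that value, every pig gene, up to 4 members of each list with the largest absolute ratio under the same minimum, and any gene at 0 in one strain and above that median in the other. The genes ompA, fliO, rcsD, rcsC, gyrA, flhD, flhC, fliA, fliC, fliR, flgA, cheZ, metR, mmuM, cueR, copA and SMWW4_v1c31150 fall outside the rule and were chosen after their values were seen.

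The calculations were tested on simulated counts for the SK68 and JNB5-1 comparison, drawn from the real means and depths, with 4137 genes past the filter. All 50 genes simulated at each of 3-, 6- and 12-fold came out at 2-fold or more, as did 3 of the 50 at 1.5-fold (1 of the 50 fell below the filter) and 26 of 3938 unchanged genes. The 95% intervals held the simulated ratio for 95.9% of genes, and 4% of 200 unshifted lists fell outside the central 95% range. The simulated counts had counting error only and genes that varied separately, as the intervals and percentiles assume. These values therefore check the calculation. They say nothing about the spread between cultures or about neighbouring genes that vary together.

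Alternatives were other pseudocounts (0.1 and 5), no filter and a minimum of 100 counts, DESeq2 size factors (DESeq2 1.42.0), total counts, centring on the median gene, the authors' log2 fold change, other thresholds of p and fold, and random lists matched on gene length. Added after the data were seen were counting intervals wholly beyond 2-fold, TMM without rRNA and tRNA genes, total counts without fliC, unadjusted p, other preset dispersions, and other scalings for the list medians. Under total counts the median of all genes was -0.09, and under the main scaling -0.01. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9. No reference annotation was used here, and gene names are those of the deposited table.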

Results

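RNA was sequenced from 2 strains of the bacterium *Serratia marcescens*, the wild type JNB5-1, a producer of the red pigment prodigiosin, and SK68, described in the labels only as a mutant. Both were grown in LB, a rich peptone and yeast extract broth, at 30 °C and harvested after 4 h, and rRNA was depleted before library preparation. The deposited table gives 1 count column per strain, so n = 1 for each strain and no difference described here has a replicate check. The counts summed to 9214184 in JNB5-1 and 9946151 in SK68. Of the 4907 genes in the table, 4144 had at least 10 counts over both strains and were compared. Among these, the median count was 399 in JNB5-1 and 425 in SK68. The most counted gene was ompA, encoding an outer membrane protein, in JNB5-1 (2.77% of counts) and fliC, encoding the flagellar filament protein, in SK68 (4.22%, against 0.930% in JNB5-1). The question addressed is how gene expression differed between the mutant and its wild type.

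The transcript of rcsB, encoding the response regulator of the Rcs envelope stress phosphorelay, was the one with the lowest ratio in SK68. Flagellar and chemotaxis genes, the prodigiosin genes and some sulfate assimilation genes were at higher levels in SK68 and envelope stress genes at lower levels. Among single genes, galT, galK and ulaA of sugar use were higher and puuE, paaA and xylE lower. Of the 4144 genes compared, 341 were at least 2-fold higher in SK68 and 218 at least 2-fold lower, so that 61.0% of the genes beyond 2-fold were higher. The other 3585 genes, or 86.5%, lay within 2-fold, and the median log2 ratio over all compared genes was -0.01. The 95% counting interval lay wholly beyond 2-fold for 208 higher and 95 lower genes. The authors' deposited table holds unadjusted p-values only, and every adjusted p given below was computed from them here. In the authors' deposited table, whose p-values match edgeR's exact test with a preset dispersion and which compares these libraries and not the conditions, 86 genes were higher and 32 lower at 2-fold and a Benjamini-Hochberg adjusted p of 0.05.

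**Figure D1:**
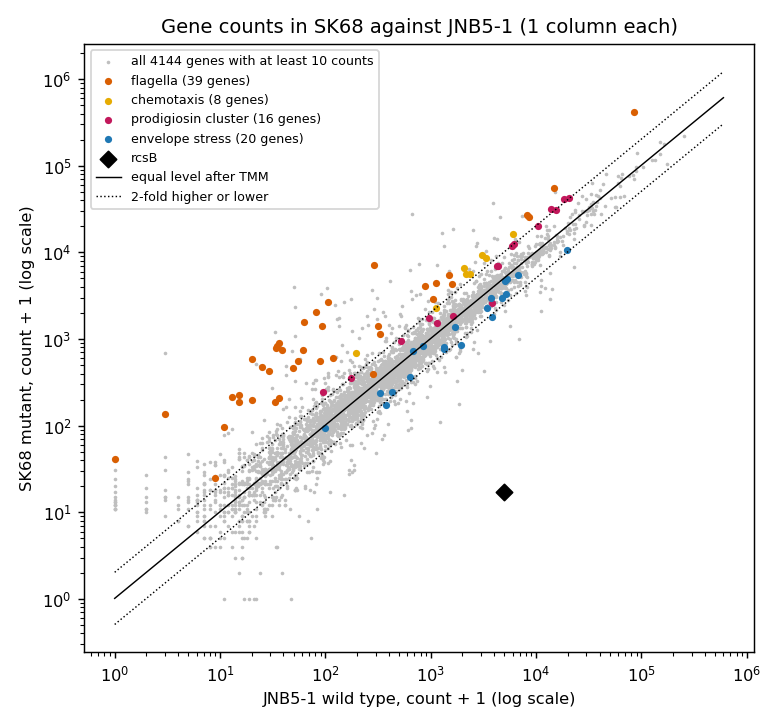
Counts per gene plus 1 in SK68 (vertical axis, log scale) against JNB5-1 (horizontal axis, log scale) for the 4144 genes compared, 1 point per gene and 1 column per strain, with flagellar, chemotaxis, prodigiosin cluster and envelope stress genes and rcsB coloured. The solid line marks equal levels after scaling and the dotted lines 2-fold; rcsB lies far below with 16 counts in SK68 against 4936 in JNB5-1.

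The rcsB gene had 4936 counts in JNB5-1 (822.9 FPKM) and 16 in SK68 (2.47 FPKM), a level in SK68 of 0.319% of that in JNB5-1 with a 95% counting interval of 0.182% to 0.518%. It spans positions 3646793 to 3647443 in the file's coordinates and is annotated as a DNA-binding response regulator; its chromosome and genome build are not given in the sources used here. In the authors' deposited table its log2 fold change was -8.28. The genes beside it differed little: rcsD, the phosphotransfer protein of the same system, which overlaps rcsB and ends at position 3646800, had a log2 ratio of -0.09 (1448 and 1380 counts in JNB5-1 and SK68). The sensor kinase gene rcsC had -0.21 (497 and 438 counts), and gyrA, encoding a subunit of DNA gyrase, -0.14. The list of Rcs and exopolysaccharide genes as a whole did not stand apart, with 10 measured members, a median log2 ratio of -0.12 and a percentile of 16.7 among random lists matched on expression. Its accessory regulator rcsA had a log2 ratio of 0.86 (905 and 1671 counts).

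Flagellar genes were higher in SK68 almost throughout. Of the 39 measured members of the flagellar list, 38 were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.30 (95% interval over members 2.27 to 4.03), or 9.84-fold. All random lists of the same size and expression had a lower median (percentile 100). Many members lie side by side, which neither the interval nor the percentile allows for. Among the members named by their ratio, flgG, a rod protein, had 104 counts in JNB5-1 and 2691 in SK68 (log2 ratio 4.66, counting interval 4.39 to 4.97), flgD, needed for hook assembly, 80 and 2039 (4.63), and fliI, the export ATPase, 19 and 584 (4.85). The motor switch gene fliM had 35 and 889 counts, and flgB 62 and 1571. The gene fliR of the export gate had 0 counts in JNB5-1 and 40 in SK68. The filament gene fliC had 85668 and 419336 counts, 4.82-fold higher. The master regulator genes flhD (88 and 563 counts, log2 ratio 2.64) and flhC (331 and 1150 counts, 1.77) and the sigma factor gene fliA (35 and 208 counts, 2.51) were also higher. The member within 2-fold was flgA, with 285 and 398 counts. In the authors' deposited table, 27 of the flagellar genes were higher at 2-fold and an adjusted p of 0.05.

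Chemotaxis genes were higher by smaller factors. Of 8 measured members, 7 were at least 2-fold higher, with a median log2 ratio of 1.38 (0.99 to 1.78) and a percentile of 100. The 8 genes lie side by side, and neither the interval nor the percentile allows for neighbours that vary together. The response regulator gene cheY had 194 counts in JNB5-1 and 681 in SK68 (log2 ratio 1.78), the coupling protein gene cheW 2051 and 6622 (1.67), the kinase gene cheA 3091 and 9256 (1.56), and the receptor gene tap 6078 and 16295 (1.40). The member just within 2-fold was cheZ (0.99). At 2-fold and an adjusted p of 0.05, 0 chemotaxis genes were called in the authors' deposited table.

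The prodigiosin biosynthesis genes were higher in SK68 by a factor close to 2. All 14 pig genes had a log2 ratio above 0, from 0.16 for pigN to 1.35 for pigG, with a median of 0.96 or 1.95-fold. Together they took 1.12% of counts in JNB5-1 and 2.11% in SK68. The genes pigE (18480 and 40863 counts, log2 ratio 1.12, counting interval 1.10 to 1.15) and pigH (20606 and 42730 counts, 1.03, interval 1.00 to 1.05), both annotated as aminotransferases, were among 5 at least 2-fold higher. The others of the 5 were pigF, an O-methyltransferase with 13861 and 31380 counts, pigG, a peptidyl carrier protein with 93 and 242, and pigK with 174 and 359. Just under 2-fold were pigD (15411 and 31150 counts, log2 ratio 0.99), pigI (0.97), pigJ (0.96) and pigC, encoding the enzyme that condenses the final precursors (10383 and 20260 counts, 0.94). Lower ratios were found for pigL (0.85), pigM (0.84), pigA (0.71) and pigB (0.68). The flanking gene cueR, a copper efflux regulator, had 0.41, and copA, a copper transporter on the other flank, -0.58. With both flanking genes, the list of 16 had a median of 0.95 (0.68 to 1.03) and a percentile of 100. The pig genes lie side by side, and neither the interval nor the percentile allows for neighbours that vary together. Because the ratios straddle 2-fold, the number of pig genes beyond it was between 3 and 5 across the scalings tried. In the authors' deposited table, the smallest unadjusted p of edgeR's exact test among the pig genes was 0.0506, for pigG, and 0 were called.

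**Figure D2:**
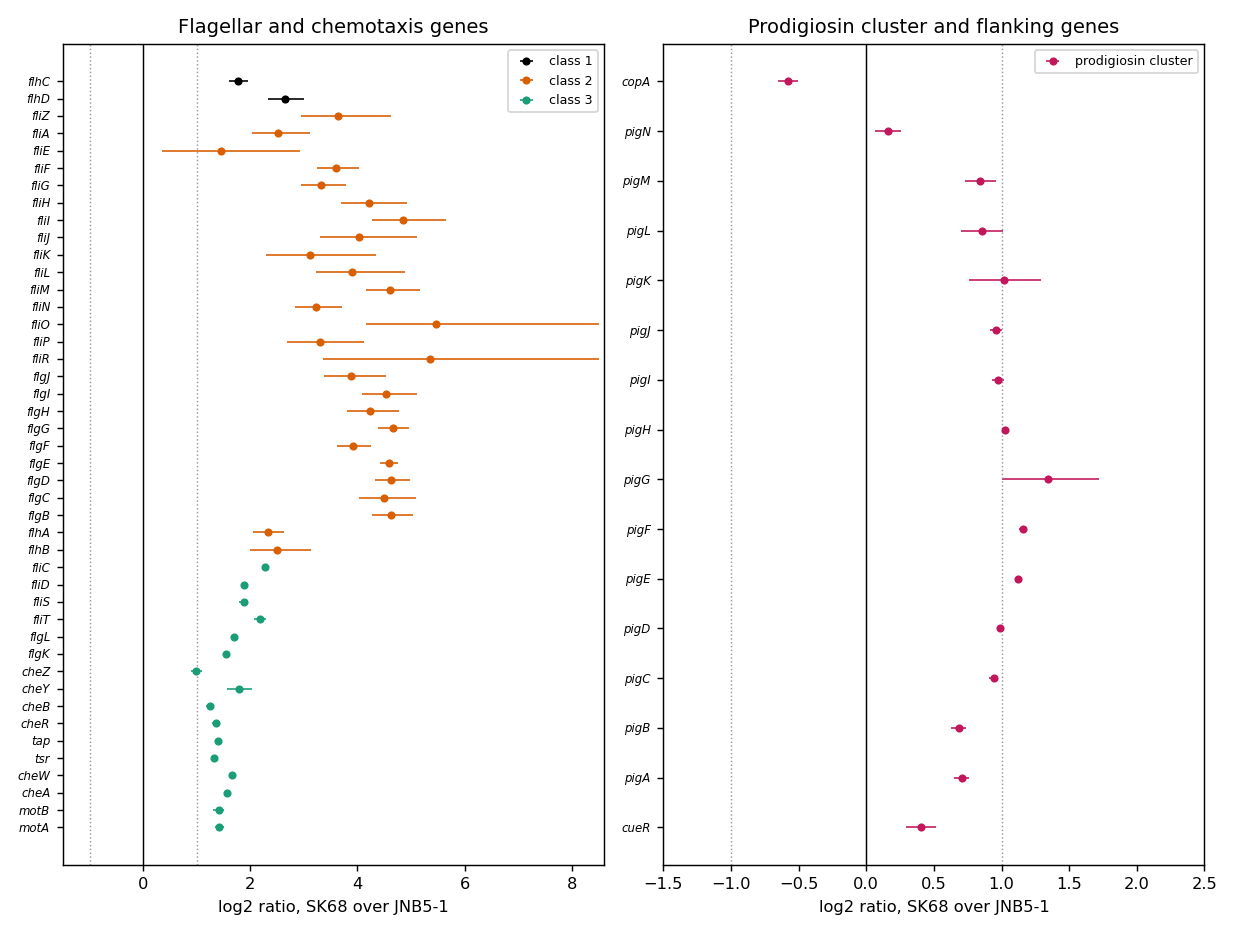
Log2 ratio of SK68 over JNB5-1 (horizontal axis) for flagellar and chemotaxis genes placed in a class (left) and the prodigiosin cluster with its flanking genes (right), 1 gene per line. The left panel does not hold the measured flagellar genes placed in no class, flgA among them. Points are ratios with a pseudocount of 1 from 1 column per strain, that of fliR resting on 0 counts in JNB5-1. Bars are 95% counting intervals, cut short at the right edge for fliO and fliR, whose upper bounds lie beyond the axis. Dotted lines mark 2-fold, and all 14 pig genes lie above 0.

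Part of the cysteine and sulfate list was higher in SK68. Of 27 measured members, 11 were at least 2-fold higher, 16 lay within 2-fold and 7 had a log2 ratio below 0, the lowest -0.87, with a median log2 ratio of 0.62 (0.09 to 2.23) and a percentile of 99.99. Among members with enough counts to be named, cysN, cysH and cysD had the largest ratios. The sulfate adenylyltransferase gene cysN had 286 counts in JNB5-1 and 2250 in SK68 (log2 ratio 2.95), and cysD, for the other subunit, 251 and 1434 (2.49). The phosphosulfate reductase gene cysH had 245 and 1855 (2.89), and the transporter gene cysA came after them (207 and 1015, 2.26). Of the list, 6 members were higher in the authors' deposited table at 2-fold and an adjusted p of 0.05.

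Among the called genes with enough counts to be named, those with the largest ratios in SK68 included several annotated to sugar uptake and use. Of a phosphotransferase system annotated to ascorbate, SMWW4_v1c34300, a IIB component, had 2 counts in JNB5-1 and 691 in SK68 (log2 ratio 7.83, counting interval 6.55 to 11.46), ulaC 49 and 3937 (6.28) and ulaA 660 and 27530 (5.36). The galactose genes galT (51 and 2315 counts, 5.45), galK (89 and 3348, 5.19) and galM (32 and 1191, 5.15) and mglA of the galactoside transporter (103 and 3836, 5.18) were also higher, as was mglC (148 and 2679, 4.15). In the list of sugar transport and maltose genes, 8 of 25 measured members were at least 2-fold higher and 0 lower, among them the maltoporin gene lamB (648 and 3595 counts, 2.45) and mglB (4239 and 14460, 1.75). The list's median was 0.23 (-0.17 to 1.03), at percentile 99.3. Of this list, 3 members were higher in the authors' deposited table at 2-fold and an adjusted p of 0.05.

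Envelope stress genes were lower in SK68 by small factors. Of 20 measured members, 19 had a log2 ratio below 0, 3 were at least 2-fold lower and 0 higher, and the median was -0.65 (-0.83 to -0.32), below that of all 10000 random lists. The phage shock genes pspA (1952 counts in JNB5-1 and 846 in SK68, -1.23) and pspB (376 and 174, -1.13), cpxP of the Cpx response (3846 and 1816, -1.11) and rseA, the anti-sigma factor of sigma E (19703 and 10673, -0.91), had the lowest ratios among members counted well enough to be named. Methionine genes had a median of -0.52 (-0.72 to 0.16) at percentile 0.03, with 2 of 15 measured members at least 2-fold lower and 1 higher. The lower ones were metK, the S-adenosylmethionine synthetase gene (-1.14), and the regulator gene metR (-1.15), and the higher one was mmuM, with 3 and 14 counts (1.89, counting interval 0.36 to 4.64). Within 2-fold, metE had -0.72, metB -0.70 and metF -0.56. Peptidoglycan genes had a median of -0.22 (-0.29 to -0.07) at percentile 0.28, with 1 of 31 beyond 2-fold, the transglycosylase gene mltD (2225 and 1094 counts, -1.05). The percentile was 2.90 against random lists matched on gene length. Of these 3 lists, 0 members were called from the authors' deposited table.

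Among the calls with the lowest ratios after rcsB, puuE, a GABA aminotransferase, had 3179 counts in JNB5-1 and 426 in SK68 (log2 ratio -2.92, counting interval -3.07 to -2.78), and SMWW4_v1c42690 next to it, a succinic semialdehyde dehydrogenase, 1842 and 179 (-3.38). Another gene with that product, SMWW4_v1c31150, had 7971 and 5289 (-0.62). The phenylacetate oxygenase gene paaA had 607 and 88 counts (-2.80). The sugar transporter gene xylE had 6817 and 1001 (-2.79), and SMWW4_v1c46160, a methylmalonate-semialdehyde dehydrogenase, 11061 and 2105 (-2.42). SMWW4_v1c17610, an extracellular endonuclease, had 642 and 115 counts (-2.49). For puuE, SMWW4_v1c42690, paaA, xylE, SMWW4_v1c46160 and SMWW4_v1c17610 the Benjamini-Hochberg adjusted p from edgeR's exact test on the authors' deposited table was between 0.000336 and 0.0223. Others among the lowest were SMWW4_v1c18870, a hypothetical protein (1215 and 109 counts, -3.49), SMWW4_v1c30380, a colicin-like protein (1759 and 323, -2.47), and SMWW4_v1c43640, an O-antigen polymerase (344 and 70, -2.30).

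Ribosomal protein genes had a median log2 ratio of -0.16 (-0.29 to -0.06) at percentile 1.17, with 0 of 45 beyond 2-fold. Respiration genes had -0.16 at percentile 3.78 and tricarboxylic acid cycle genes 0.16 at percentile 95.3, also with 0 beyond 2-fold, and gltA, the citrate synthase gene, had 46429 and 80435 counts (0.77). Like the respiration and tricarboxylic acid cycle medians, those of the remaining lists lay within the central 95% of medians of random lists. They were 0.21 for cold shock, 0.08 for regulators of prodigiosin, 0.03 for oxidative stress, -0.01 for fatty acid degradation, -0.02 for heat shock, -0.03 for proline, serine and glycine metabolism, -0.09 for multidrug efflux, -0.10 for glycolysis and fatty acid synthesis, -0.10 for iron acquisition and -0.12 for anaerobic metabolism. The medians of 2 lists, regulators of prodigiosin and oxidative stress, changed sign with the scaling. Single members of these lists went both ways: the catalase genes katG (7800 and 3584 counts, -1.15) and katE (176297 and 104242, -0.78) were lower in SK68, as were pstS of phosphate uptake (3968 and 1942, -1.05) and the RNA helicase gene deaD (13655 and 5767, -1.27). The ferrous iron transport gene feoA (105 and 360 counts, 1.74), cspE (1764 and 3919, 1.13) and the regulator gene slyA (185 and 403, 1.10) were higher.

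**Figure D3:**
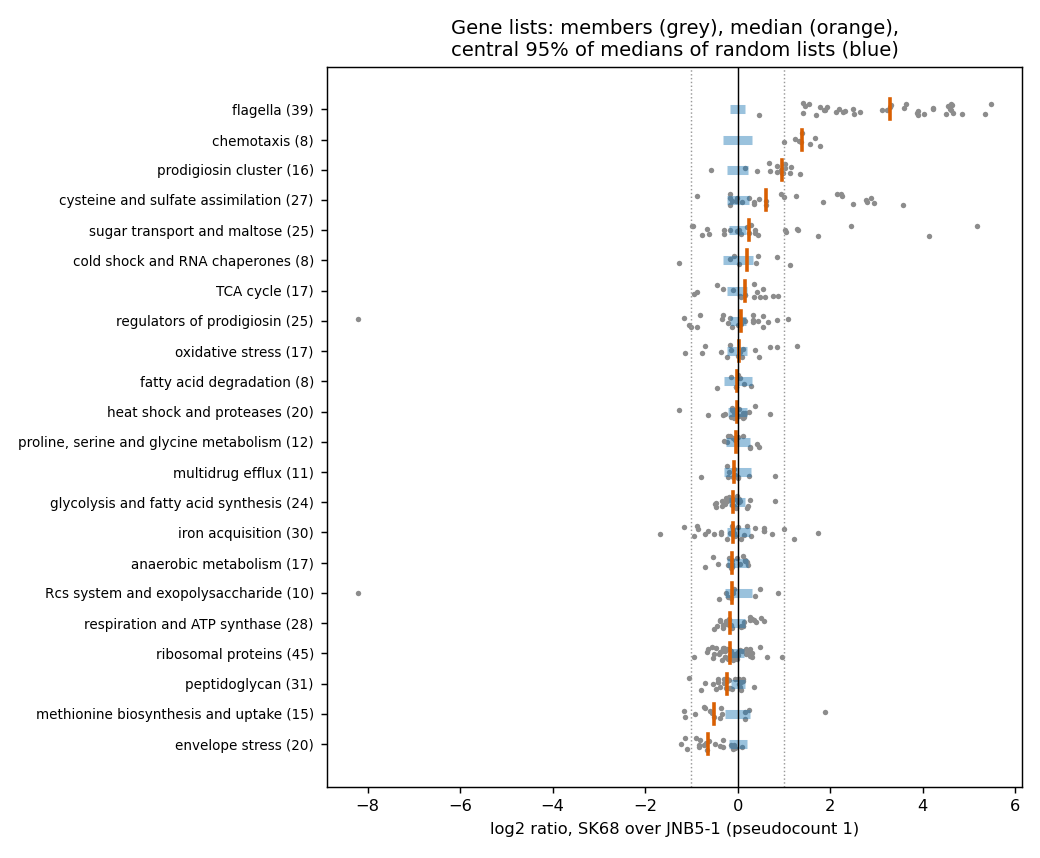
Log2 ratio of SK68 over JNB5-1 (horizontal axis) for the members of each of the 22 gene lists with enough measured genes, with the number measured in brackets. Grey points are genes, orange lines are list medians and blue bars hold the central 95% of medians of random lists matched on expression; the flagellar median of 3.30 lies highest and the envelope stress median of -0.65 lowest.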

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

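Counting intervals beyond 2-fold, TMM without rRNA and tRNA genes, total counts without fliC, unadjusted p, other dispersions, and total counts and DESeq2 size factors for list medians were chosen after the data were seen. No result beyond 2-fold or outside the central range of random lists changed direction; the medians of 2 lists near 0, regulators of prodigiosin and oxidative stress, changed sign with the scaling. The 341 higher genes became 208 and the 218 lower genes 95 when the whole counting interval had to lie beyond 2-fold, and 127 lower genes were left at a minimum of 100 counts, which leaves fewer genes. The share of higher genes was 68.7% with such intervals and 54.5% under total counts. Of the calls from the authors' deposited p-values, 86 higher and 32 lower became 210 and 106 at unadjusted p, 184 and 87 at a preset dispersion of 0.04, and 55 and 6 at 0.16, while the lower calls numbered 11 at an adjusted p of 0.01. Under total counts the peptidoglycan median was -0.31 and the anaerobic median -0.20, each just outside the interval of its median; the cause was the scaling, which shifts all genes alike. Over the alternatives, the flagellar median ranged from 3.13 to 3.31, the prodigiosin cluster from 0.86 to 0.96 and envelope stress from -0.73 to -0.64. Of the other comparisons, 460 named-gene ratios and 108 list medians stayed within their intervals. No paired analysis was possible because each strain has 1 column, and for the same reason replicate tests with edgeR or DESeq2 and leaving out replicates were not run.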

Other observations

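All tests and gene groups in this part were chosen after the values had been seen.

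Of 8 genes found by a few product words for secreted degradative enzymes, 5 were at least 2-fold lower in SK68 and 3 within 2-fold. Their median log2 ratio was -1.69, with no set test. The words left out a phospholipase gene, SMWW4_v1c37820, which was higher in SK68 (log2 ratio 3.12), so the 8 need not stand for all such enzymes. The metalloprotease gene SMWW4_v1c02160 had 22662 counts in JNB5-1 and 6856 in SK68, the extracellular lipase gene SMWW4_v1c22380 12030 and 3926, and the chitinase C1 gene SMWW4_v1c11910 1980 and 444. Serralysin (SMWW4_v1c32410, -0.85), a secreted alkaline metalloprotease (SMWW4_v1c21130, -0.69) and chitinase B (SMWW4_v1c35890, -0.68) lay within 2-fold, and of the 8 the endonuclease gene SMWW4_v1c17610 alone was called from the authors' deposited table. Of 17 putrescine and GABA genes found by product, 12 lay within 2-fold, 4 were lower and 1 higher, with a median of -0.34. The phospholipase gene SMWW4_v1c37820 (1331 and 11808 counts) and a filamentous hemagglutinin gene (SMWW4_v1c44500, 781 and 7275 counts) were higher in SK68, each with its neighbour.

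Several metabolic loci were picked out because their genes lay beyond 2-fold as blocks, so their medians describe that choice and are no test. The 4 dihydroxyacetone genes were higher in SK68 (median 3.34), with gldA at 3923 and 36794 counts, as were 6 of 7 citrate lyase genes (median 2.82) and the 6 bcs genes of cellulose synthesis (median 1.23). The bcs ratios lay only a little past 2-fold, from 1.01 to 1.47. Of the citrate lyase genes, citD, citG and citX had only 0, 10 and 14 counts in JNB5-1. Phenylacetate degradation genes were lower, 11 of 14 by at least 2-fold (median -1.77), as were 9 of 12 genes of an inositol locus (median -1.81). Over the whole table, 23 runs of at least 4 adjacent genes lay beyond 2-fold in the same direction, 18 higher and 5 lower, with 151 genes. In 1000 shuffles of gene order the number of such runs was at most 2, with a median of 0. Shuffling single genes separates neighbours that are read together, so a low number was fixed in advance and is no support for a strain difference. The runs also include flagellar, chemotaxis, pig and cys genes already described. One of the lower runs was a fimbrial locus of 11 genes (median -2.02), many with few counts in SK68. Of 19 genes with fimbrial products elsewhere, 12 lay within 2-fold, 6 were higher and 1 lower.

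The flagellar genes were higher in SK68. Scaling by a few abundant genes is argued against, since the lowest flagellar median over the scalings was 3.21. One hypothesis is that low rcsB may raise flhD and flhC, known regulators of these genes; their lowest counting bound was 1.60 on the log2 scale, but both belong to the genes to be explained, so this does not bear on it and it stays open. A different growth stage at harvest could not be excluded. The ribosomal protein median was -0.16 (-0.29 to -0.06), and even a median near 0 would not have excluded it for these cultures. With 1 column per strain, the mutation and any difference between cultures cannot be told apart.

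The 26 flagellar genes placed in class 2 from textbook knowledge had a median of 3.97 (3.91 with fliR, at 0 counts in JNB5-1, set against a floor of 3 counts). The 16 flagellar and chemotaxis genes placed in class 3, made after them, had 1.55. Not every flagellar gene was placed in a class. Among those in none was flgA, which had the lowest log2 ratio of the flagellar list (0.46), so the class 2 values do not cover it. Within class 3, the 8 chemotaxis genes had a median of 1.38 and the 8 flagellar genes 1.79. Median counts in JNB5-1 were 33.5 in class 2 and 2270 in class 3. Counting noise at low counts is argued against as the whole cause, as the median lower counting bound of class 2 exceeded the median upper bound of class 3 by 1.76 on the log2 scale, and by 1.54 without the chemotaxis genes. No biological explanation was tested for this difference. The lowest class 2 gene, fliE (1.45, counting interval 0.36 to 2.93), had 8 and 24 counts and lay below class 3 genes such as fliC (2.27). Every other class 2 gene lay above all of class 3, the next lowest being flhA (2.32).

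The rcsB transcript was at 0.319% of its JNB5-1 level in SK68. Lost coverage of the region is argued against, since the largest absolute log2 ratio among the 4 nearest genes was 0.21. A candidate explanation is that SK68 carries a change in or at rcsB, which the labels neither state nor exclude and which was not tested. The remaining 16 counts could come from wild-type RNA or reads in the SK68 library: the 28 genes with 0 counts in SK68 had 221 counts in JNB5-1, so that such carry-over would give only 0.716 counts over all of them. That is too few to decide, and genes chosen for having 0 counts in SK68 could not have shown carry-over in any case.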
